A study of Mus musculus with 47 samples.

How the data were processed

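RNA from the leukaemic spleens of 47 mice was measured on Affymetrix Mouse Genome 430 2.0 arrays, 1 array per mouse. Per the labels' protocols, spleen tissue was frozen at necropsy, RNA was purified with a column kit, and labelled RNA was made with a 3′ in vitro transcription kit, which copies RNA from its 3′ end. The deposited values are log2 expression values that the authors made with the RMA algorithm of the affy package in R 2.15, per the submitters' processing notes. RMA subtracts background, quantile normalizes the arrays against each other and summarises the probes of a probe set. Scanner files were not used here.

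The table held 45101 probe sets, of which 64 were array controls, with 0 missing values. Values ran from 4.78 to 12.99. The 25th percentile of all values was 5.08 and the array medians lay between 5.19 and 5.24, so most probe sets sat close to a common floor. Differences of dim genes are therefore compressed, and log2 differences near the floor understate the change in RNA. The arrays were all different from one another: correlations between pairs ran from 0.903 to 0.991, and 0 pairs held identical values. For arrays, the number of mice limits the precision.

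Probe sets were named from the platform annotation. A single gene was named for 34945 probe sets and several genes for 932, and 9160 probe sets were unnamed here; only probe sets with 1 gene were used. Of these, 34741 had a gene number in the RefSeq gene table of GRCm38.p6, and 0 symbols changed when updated through it. The genome build of the array annotation was not given in the sources used here, so no positions are printed, and the table served for names only. Where a gene had several probe sets, the one with the highest mean over the 47 arrays was kept, which gave 18193 genes. Genes above log2 5 in at least 9 arrays were tested, which left 18178 genes and removed 15.

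Groups came from the labels: whether the tumour had a transposon insertion in Erg, the sex of the mouse, the line that carried the transposon and the age at necropsy. The 2-digit number in a tumour identifier (7, 8 or 9 with a leading zero) has no stated meaning and was used only as an alternative block. The unit of age was not given. Every mouse is a separate animal, so the spread between arrays of a group includes the spread between tumours. Which array belongs to which label was taken from the deposited column names. The sex labels did not match the sex-chromosome transcripts of the arrays, as the report describes, so groups are named by their labels throughout.

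Gene tests used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The Erg comparison had line and sex as covariates; line had Erg and sex, sex had Erg and line, and age had all of these. Interactions of Erg with line and of Erg with sex were tested as product terms. The procedure was tested on simulated data: the arrays were shuffled against the labels and 200 genes with a mean above 6 were shifted in the arrays labelled with an Erg insertion (26 against 21 arrays, 18178 genes, 10 runs per shift). On average, 83.4% of genes shifted by 0.5 log2 units were recovered, 97.65% of those shifted by 1 unit and 99.85% of those shifted by 2 units, with 4.7 to 6 false calls on average.

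Before the data were examined, 21 gene lists were fixed. Blood and tissue types were erythroid, megakaryocyte and platelet, stem and progenitor, neutrophil and granule, monocyte and macrophage, mast cell, basophil and eosinophil, B cell, plasma cell, T and NK cell, dendritic cell and MHC class II, and stroma and endothelium. The others were haem synthesis and iron, cell cycle, interferon-stimulated, p53 targets, JAK-STAT targets and cytokine signalling, ETS family, leukaemia oncogenes and suppressors, immediate early and heat shock, hypoxia and glycolysis, and sex chromosome. Lists were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. The genes to be named for the Erg comparison were also fixed then: every Erg probe set, the 12 largest positive and negative differences past the threshold, and of each list the 4 members with the smallest adjusted p past the threshold, or the 2 with the smallest p where none passed. For other comparisons, up to 5 genes per direction past the threshold were to be named. Members of the sex chromosome list could be named anywhere. A list mean is the mean of its members' standardised values over the 47 arrays.

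Single values, ages and principal component scores were compared with two-sided permutation tests of 100000 resamples, and with exact permutation tests where a group had fewer than 10 mice. Correlations have Pearson's r and Spearman's rho with permutation p-values, and were repeated without the 2 arrays farthest from the median of the first measure. The sex check used the brightest Xist probe set, taken as present above log2 7, and the mean of 3 Y-linked probe sets, for Eif2s3y, Kdm5d and Uty, taken as present above 5.5; both levels were set after the values were seen, inside gaps between the arrays. The match was set against 100000 random pairings of labels and arrays. RNA quality was measured as the 3′ minus 5′ difference of the Gapdh and beta-actin control probe sets. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.

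Alternatives covered the filter, the choice of probe set, the covariates, subsets of mice by label, RNA quality, lymphocyte content, further normalization, the variance model and array weights. Added after the data were seen were a filter at log2 6, a fit without the sex label, a fit on the arrays whose sex label matched, Erg correlations over all 47 arrays, the sex check itself, the description of marker levels across arrays, 4 lists of precursor and mature B and T cell genes, and the correlation of every gene with Erg, from which Ets1 was singled out. A test by chromosome was planned for called genes and was not run, because no gene was called.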

Results

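The data were 47 array profiles of leukaemic spleens, 1 from each of 47 mice in which the Sleeping Beauty transposon had been mobilised in all tissues. A mobile transposon inserts into the genome and can switch genes on or break them, so each leukaemia carries its own set of insertions. All mice had the same diagnosis label, an undifferentiated myeloid leukaemia at its terminal stage. The labels gave an insertion in Erg for 26 tumours and none for 21. Erg encodes an ETS family transcription factor of blood stem cells and megakaryocytes. There were 25 mice labelled female and 22 labelled male, and 26 mice of transposon line 6070 and 21 of line 6113. In line 6070, 17 mice had the Erg insertion label and 9 did not; in line 6113, 9 did and 12 did not. The share with an insertion did not differ detectably between the lines (two-sided Fisher's exact test, p = 0.149) or between the labelled sexes (p = 0.770).

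Xist, the RNA that silences an X chromosome in female cells, and the Y-linked genes Eif2s3y, Kdm5d and Uty divided the arrays cleanly. Xist lay between 8.29 and 10.05 on the log2 scale in 25 arrays and between 5.16 and 5.72 in 22. The mean of the Y-linked genes lay between 4.95 and 5.34 in the arrays with Xist and between 5.60 and 6.32 in those without. No array had both or neither. The totals equal the numbers of labelled females and males, but the arrays and labels did not pair: Xist was absent from 12 of the 25 arrays labelled female and present in 12 of the 22 labelled male. In all, 23 arrays matched their label and 24 did not. Random pairing gave 23.6 matches on average, with a central 95% range of 17 to 31. Among the arrays that disagreed, 16 were labelled with an Erg insertion and 8 without, and 12 came from each line. The labels are therefore used here as given, with arrays named by their labels, and any direction drawn between labelled groups stands beside this mismatch. Comparisons of labels with each other, and of genes with each other across arrays, do not use the pairing of arrays and labels. If only the sex labels are out of order, comparisons of sex with other labels are affected as well.

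**Figure D1:**
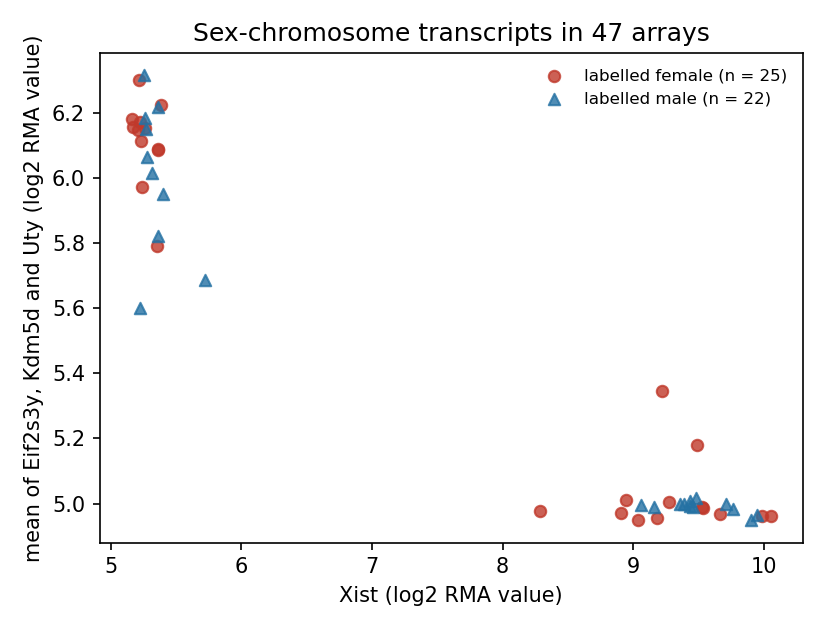
Xist (horizontal axis, log2 value) against the mean of Eif2s3y, Kdm5d and Uty (vertical axis, log2 value) in 47 arrays, 1 point per array, with colour and shape giving the labelled sex. Both clusters hold both labels: 12 arrays labelled female lie among the 22 without Xist, and 12 labelled male among the 25 with it.

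Taken without regard to labels, the spleens differed in the levels of genes of several blood lineages. Genes in this paragraph and the next are the 4 most variable members of each list, and n is 47 arrays throughout. That rule was chosen after their values were seen and favours wide ranges, so the ranges describe these genes only. All arrays were of leukaemic spleens, so RNA of tumour cells and of other spleen cells cannot be told apart. Of the erythroid list, Car1, an erythroid carbonic anhydrase, had a median of 10.31 (range 6.20 to 11.57) and was above log2 7 in 45 arrays. The erythroid transcription factor Klf1 (median 9.14) was above this level in 43 arrays, the anion exchanger Slc4a1 (9.17) in 45 and Nfe2 (8.72) in 39. The platelet chemokine Pf4 was above it in 43 arrays (median 9.27) and Ppbp in 26 (range 5.07 to 10.80). The platelet receptor genes Gp1bb and Itgb3 were above it in 9 and 10 arrays. Of the monocyte and macrophage list, Lyz2, Lyz1 and Ctss exceeded log2 7 in all 47 arrays and Csf1r in 44. Neutrophil genes ran over a wide range, with S100a8 from 5.05 to 11.99 and S100a9 from 5.30 to 11.78, and Chil3 and Ngp above log2 7 in 17 arrays each.

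Lymphoid, eosinophil, progenitor and leukaemia genes ranged from bright in every spleen to bright in a few. In the B cell list, Ighm was above log2 7 in all 47 arrays, Pou2af1 in 14, Blnk in 13 and Cd79b in 12. In the plasma cell list, Mzb1 was above it in 17 arrays, Jchain in 19, Tnfrsf13b in 2 and Irf4 in 1. In the T and NK list, Lef1 was above it in 15 arrays, Il7r in 11, Gzma in 10 and Cd3d in 9, with Cd3d reaching 10.23 against a median of 5.54. Genes of MHC class II were intermediate, with H2-Aa above it in 43 arrays, H2-Ab1 in 26 and H2-Eb1 in 21, and Ly6d in 4. The eosinophil and basophil genes Prg2, Mcpt8, Epx and Fcer1a were above it in 3, 4, 1 and 2 arrays, with Prg2 at 11.78 in the highest. Among stem and progenitor genes, Lmo2 was above it in 46 arrays, Sox4 in 24, Gata2 in 16 and the receptor kinase Flt3 in 9, reaching 10.31 from a median of 5.33. In the list of leukaemia genes, Eras, a Ras family gene of embryonic stem cells, had a median of 5.04, was above it in 8 arrays and reached 11.01. Notch1 was above it in 6 arrays and Ets1 in 34.

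**Figure D2:**
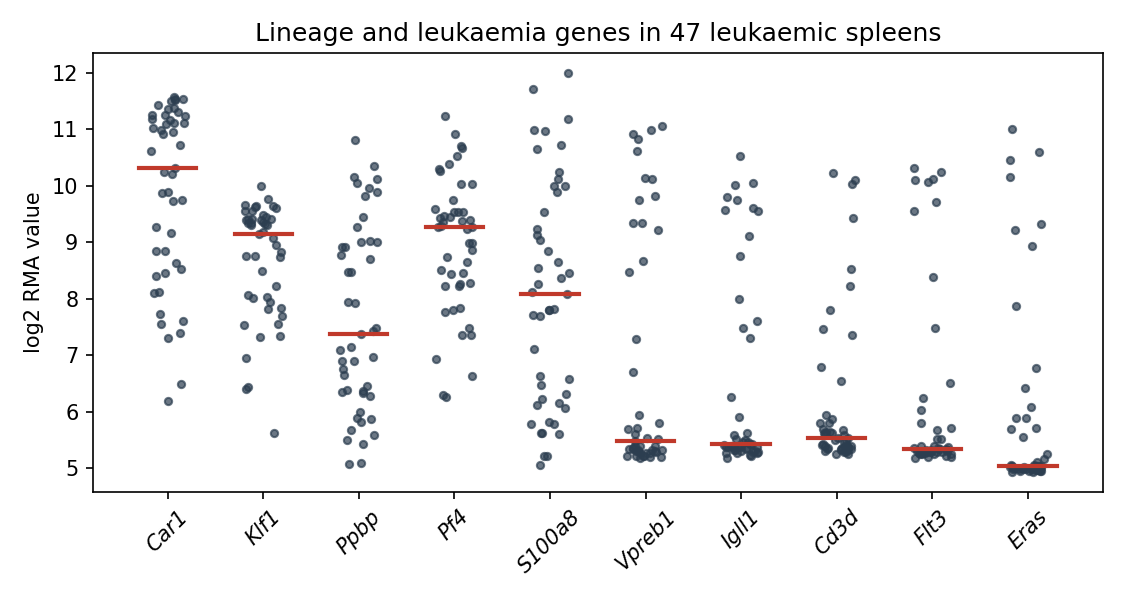
Log2 values (vertical axis) of 10 lineage and leukaemia genes in 47 leukaemic spleens, 1 point per array, with the median as a red line. Car1 and Klf1 are high in most arrays, while Vpreb1, Igll1, Cd3d, Flt3 and Eras lie near the floor in most and above log2 7 in 15, 14, 9, 9 and 8 arrays.

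Along the largest axis of variation, the erythroid list mean rose while lymphoid and myeloid list means fell. Over the 47 arrays, rho with principal component 1 was 0.64 for erythroid, -0.79 for B cell and -0.71 for T and NK. It was -0.72 for neutrophil and granule and -0.68 for monocyte and macrophage. Principal component 1 held 35.7% of the variance over the 18178 tested genes, component 2 held 9.71% and component 3 held 7.15%. The genes with the largest weights at one end of component 1 included Col5a1 and Car1, of which only Car1 stands in the erythroid list. At the other end were Vpreb1 and Igll1, which encode the surrogate light chain of B cell precursors, with Plac8, Coro1a, Mzb1 and Sox4. Component 2 ran from the T cell genes Trbv1, Cd3d, Cd3g, Bcl11b and Thy1 to Vpreb1, Igll1, Ppbp, S100a8, S100a9 and Flt3. Component 3 ran from Igll1, Xist, Pou2af1 and Blnk to Chil3, S100a8, S100a9, Prg2 and Camp. None of 9 tests of these 3 components against the Erg, line or sex labels passed Benjamini-Hochberg adjustment (permutation tests, smallest p = 0.168, smallest adjusted p = 0.854). The erythroid list mean fell as the T and NK list mean rose (r = -0.45, permutation p = 0.00213, adjusted p = 0.0192 over 9 relations; rho = -0.41, p = 0.00493; n = 47), and r was -0.61 without the 2 arrays farthest from the erythroid median. By rho, the dendritic cell and MHC class II list (rho = -0.47, permutation p = 0.00102, adjusted p = 0.00918) and the plasma cell list (rho = -0.42, p = 0.00377, adjusted p = 0.0148) also passed, while by r they did not (r = -0.30, p = 0.0402, adjusted p = 0.121, and r = -0.33, p = 0.0200, adjusted p = 0.0900). Without the 2 farthest arrays, the plasma cell (r = -0.35, adjusted p = 0.0433) and megakaryocyte and platelet (r = 0.40 from 0.086, adjusted p = 0.0283) lists passed by r as well. The stem and progenitor list did too (r = 0.38 from 0.23, adjusted p = 0.0283), and the dendritic cell and MHC class II list did not (r = -0.32, adjusted p = 0.0565). Over all 47 arrays, the megakaryocyte and platelet list (r = 0.086, adjusted permutation p = 0.628) and the stem and progenitor list (r = 0.23, 0.172) passed neither by r nor by rho. The same held for neutrophil and granule (r = -0.17, 0.317), monocyte and macrophage (r = -0.24, 0.172) and B cell (r = -0.27, 0.136). It also held for the mast cell, basophil and eosinophil list (r = -0.035, 0.801).

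The Erg label comparison asked whether tumours labelled with an Erg insertion expressed other genes than those without. Erg itself did not differ between the labelled groups by more than the spread between tumours. The brighter of its 2 probe sets was at 6.73 ± 1.08 (SD, n = 26) in arrays labelled with an insertion and at 6.19 ± 0.79 (n = 21) in those without, a limma log2 difference of 0.56 ± 0.29 (SE, unadjusted p = 0.0580; permutation p = 0.0627). It exceeded log2 7 in 13 of the 26 arrays and in 4 of the 21. The dimmer probe set was at 5.52 ± 0.31 and 5.39 ± 0.24 (permutation p = 0.124; adjusted p = 0.124 for both probe sets). As a check of the labels, this does not separate the groups, since both held arrays near the floor and arrays above 7. The difference was 0.28 in line 6070, 0.97 in line 6113, 0.86 in labelled females and 0.24 in labelled males. It was 0.82 with age as a covariate and -0.058 in the 23 arrays whose sex label matched their transcripts. Over all alternatives the limma p ran from 0.576 to 1.0 after adjustment over all genes or probe sets tested. That adjustment is stricter than a test of Erg alone.

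**Figure D3:**
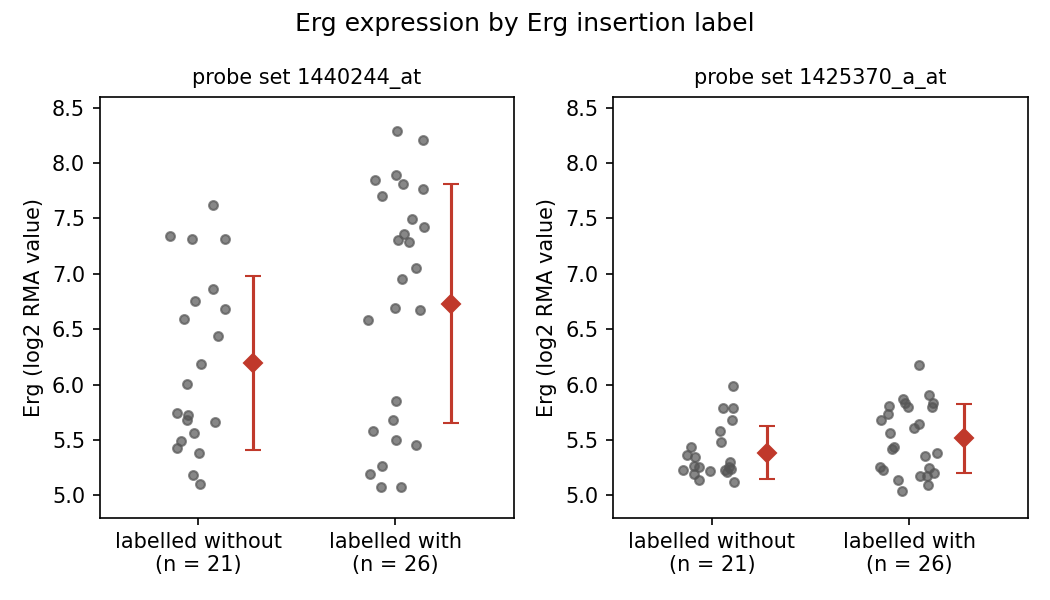
Log2 values (vertical axis) of the 2 Erg probe sets in arrays labelled without (n = 21) and with (n = 26) an Erg insertion, 1 point per array, with the mean and SD in red. The groups overlap: the brighter probe set spans 5.10 to 7.62 without and 5.08 to 8.28 with the label.

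By limma, 0 of 18178 genes were higher and 0 were lower with the Erg insertion label, and 666 had an unadjusted p under 0.05 where 908.9 are expected by chance (smallest adjusted p = 0.999). None of the 21 lists had a member past the threshold, over all genes or adjusted over the list alone. At the preset correlation, camera placed 3 lists lower in the arrays labelled with an insertion and 2 higher, and with an estimated correlation none remained: the adjusted p was 0.795 for each of the 5 (0.867 by fry). In the B cell list, 1 of 26 members had a positive difference (preset adjusted p = 1.78e-05); the complement receptor Cr2 differed by -0.20 ± 0.11 and Ighm by -0.66 ± 0.37 (log2, SE). In the plasma cell list, 2 of 11 were positive (0.0150), with Jchain at -0.61 ± 0.29 and Derl3 at -0.037 ± 0.021. In the dendritic cell and MHC class II list, 4 of 21 were positive (0.0150), with Cadm1 at -0.14 ± 0.07 and Ccl17 at -0.20 ± 0.09. In the stroma and endothelium list, 21 of 33 were positive (0.0121), with the basement membrane collagens Col4a1 at 0.30 ± 0.10 and Col4a2 at 0.22 ± 0.07. In the hypoxia and glycolysis list, 19 of 24 were positive (0.0121), with Ddit4 at 0.32 ± 0.17 and Aldoc at 0.039 ± 0.022.

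The other 16 lists were not called by the preset test, with adjusted p from 0.0829 for the erythroid and neutrophil and granule lists to 0.856 for the stem and progenitor list. Red cell genes with the smallest p were Tfrc (-0.20 ± 0.16) and Kel (-0.19 ± 0.16), and Uros in haem synthesis and iron (-0.21 ± 0.13; preset adjusted p = 0.179). Neutrophil and granule genes were Camp (-0.48 ± 0.41) and Stfa3 (-0.12 ± 0.11). Megakaryocyte and platelet genes (0.198) were Treml1 (0.33 ± 0.12) and Rab27b (0.31 ± 0.16), and stem and progenitor genes Robo4 (0.055 ± 0.021) and Myb (-0.25 ± 0.14). Monocyte and macrophage genes (0.297) were Cx3cr1 (0.12 ± 0.06) and Slc40a1 (-0.18 ± 0.12), and mast cell, basophil and eosinophil genes (0.299) Tpsb2 (-0.016 ± 0.014) and Epx (-0.30 ± 0.27). T and NK cell genes (0.668) were Klre1 (-0.028 ± 0.013) and Ccl5 (-0.28 ± 0.17). In the ETS family (0.668), Ets1 was at -0.62 ± 0.38 beside Erg itself, and among leukaemia oncogenes and suppressors (0.668), Runx1 was at 0.24 ± 0.11 and Jak1 at -0.32 ± 0.16. For that last list the median difference (0.0083) was above 0 while the mean (-0.013) and the camera test pointed down, and for the stem and progenitor list the mean (-0.025) was below 0 while the median (0.0081) and the test pointed up.

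Signalling and cell state lists behaved alike. JAK-STAT targets and cytokine signalling (preset adjusted p = 0.111) had Socs1 at 0.057 ± 0.036 and Csf2rb at 0.31 ± 0.20. The cell cycle list (0.204) had Cdk1 at -0.13 ± 0.05 and Bub1b at -0.064 ± 0.063. The interferon-stimulated list (0.531) had Oasl2 at 0.28 ± 0.18 and Zbp1 at 0.15 ± 0.10. The p53 targets (0.198) had Bbc3 at 0.15 ± 0.08 and Ptprv at 0.047 ± 0.034. The immediate early and heat shock list (0.511) had Atf3 at 0.045 ± 0.027 and Hspa8 at 0.080 ± 0.050, with a negative median (-0.011) against a positive mean (0.013) and an upward test. The sex chromosome list (0.668) had Usp9y at 0.016 ± 0.010 and Ddx3x at 0.067 ± 0.070, with a positive median (0.016) and test and a negative mean (-0.013). The 3′ minus 5′ difference of control probe sets was 1.38 ± 0.46 with the label and 1.37 ± 0.44 without (permutation p = 0.941).

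Line, sex, age and both interactions also gave 0 genes past the threshold by limma. Between arrays labelled line 6113 and line 6070, 540 of 18178 genes had an unadjusted p under 0.05 (smallest adjusted p = 0.999). Between arrays labelled female and male, 460 did, and not even Xist or the Y-linked genes passed. With the age label, 688 did. For the interaction of the Erg label with line, 1286 did (smallest adjusted p = 0.494), and for that with sex, 1079 did (0.838). By the preset camera test, 8 lists were called between the lines: B cell, megakaryocyte and platelet, monocyte and macrophage, ETS family and interferon-stimulated toward line 6113, and erythroid, haem synthesis and iron, and mast cell, basophil and eosinophil toward line 6070. The same test called 4 lists for sex and 7 for age, and the estimated correlation called 0 for each (smallest adjusted p = 0.561, 0.887 and 0.370). The Erg fold changes fitted in line 6070 and in line 6113, which share no mouse, had r = -0.19 across genes. Genes are not independent replicates, and shuffled Erg labels gave values from -0.57 to 0.68 in the central 95% of 100 draws.

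Mice labelled with an Erg insertion were older at necropsy. Their age label was 72.4 ± 12.9 (SD, n = 26, unit not given) against 56.1 ± 13.2 (n = 21), a difference of 16.3 (permutation p = 0.0001, adjusted p = 0.0003 over 3 comparisons), and 23 of the 26 were above the median of the mice without the label. The difference was 20.1 in line 6070 (n = 17 and 9, exact permutation p = 0.00124) and 12.7 in line 6113 (n = 9 and 12, exact permutation p = 0.0464). Among the 33 mice with 09 in the tumour identifier it was 13.4 (n = 16 and 17, permutation p = 0.00834), and the other numbers each held only 2 mice without an insertion. Age did not differ detectably between lines (63.9 ± 14.6 in line 6113, n = 21; 66.1 ± 16.1 in line 6070, n = 26; permutation p = 0.622) or between labelled sexes (65.6 ± 16.5 in females, n = 25; 64.5 ± 14.2 in males, n = 22; permutation p = 0.805). These values compare labels with labels and do not involve the arrays. Those by labelled sex also require that the sex labels belong to their mice.

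Among arrays labelled with an insertion, those with more Erg had lower means of the T and NK, dendritic cell and MHC class II, and neutrophil lists. Of 22 relations of the Erg level computed within the labelled groups, 3 passed Benjamini-Hochberg adjustment by Pearson's r, all among the 26 arrays labelled with an insertion. These were the dendritic cell and MHC class II list (r = -0.64, p = 0.00039, adjusted p = 0.00429; rho = -0.61, p = 0.0011), the T and NK cell list (r = -0.63, p = 0.00028, adjusted p = 0.00429; rho = -0.71, p = 0.00011) and the neutrophil and granule list (r = -0.57, p = 0.00239, adjusted p = 0.0175; rho = -0.64, p = 0.00069), all with permutation p-values. Without the 2 arrays farthest from the median Erg value, r was -0.66, -0.65 and -0.50, and 3 further relations passed: the B cell (r = -0.51, adjusted p = 0.0432) and plasma cell (r = -0.56, adjusted p = 0.0325) lists with the label and the stem and progenitor list without it (r = 0.59, adjusted p = 0.0355). By rho 5 relations passed, the others being the B cell list with the label (rho = -0.59, adjusted p = 0.0107) and the T and NK list without it. In the 21 arrays labelled without an insertion, r with the T and NK list was -0.50 (permutation p = 0.0121, adjusted p = 0.0532; rho = -0.57, p = 0.00778, adjusted p = 0.0342). The 3 lists had r of -0.65, -0.57 and -0.57 with the dimmer Erg probe set. With that probe set the call of the T and NK list without the label ended (rho = -0.38, permutation p = 0.0929, adjusted p = 0.192), and that of the B cell list with it did not (rho = -0.57, p = 0.00299, adjusted p = 0.0164). Whether the labelled groups differ in these relations was not tested. No relation of the age label with the Erg level was detected in either group (r = -0.14 and -0.30, adjusted p = 0.540 and 0.325). Over all 47 arrays, a set chosen after the data were seen, r was -0.56 for the T and NK list (rho = -0.64), -0.50 for the dendritic cell and MHC class II list (rho = -0.50) and 0.46 for the stem and progenitor list (rho = 0.43). Their adjusted permutation p over 12 relations was 6e-05, 0.00176 and 0.00302 for r, and 0.00012, 0.00144 and 0.00446 for rho. Members of the stem and progenitor list hardly varied together, with a median correlation of 0.015 between them, against 0.68 in the B cell list. Its mean therefore does not stand for a pattern shared by its members. Of the other lists, r was -0.46 for plasma cell (rho = -0.44; adjusted p = 0.00302 and 0.00444), -0.42 for neutrophil and granule (rho = -0.52; 0.00562 and 0.00084) and -0.32 for B cell (rho = -0.48; 0.0472 and 0.00187), which ended for B cell without the 2 farthest arrays (r = -0.27, adjusted p = 0.114), and monocyte and macrophage passed by rho only (r = -0.30, rho = -0.33; 0.0567 and 0.0379).

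Some list means also went with the 3′ minus 5′ difference of control probe sets over the 47 arrays, in 10 relations with permutation p-values. The mast cell, basophil and eosinophil list passed by r (0.62, p = 0.00025, adjusted p = 0.0025) and rho (0.46, p = 0.0012, adjusted p = 0.0079), and r was 0.31 (adjusted p = 0.126) without the 2 farthest arrays. The neutrophil and granule list passed by r (0.42, p = 0.00552, adjusted p = 0.0276) and not by rho (0.068, adjusted p = 0.814), and the relation rests on those 2 arrays, since r was 0.022 without them. The stem and progenitor list passed by rho (0.45, p = 0.00158, adjusted p = 0.0079) and not by r (0.32, p = 0.0300, adjusted p = 0.100; 0.36 without the 2). The erythroid list had r = 0.26 (adjusted p = 0.193) and rho = 0.25 (adjusted p = 0.318), and r was 0.41 (adjusted p = 0.0496) without the 2. The Erg level itself had r = 0.031 (permutation p = 0.840) and rho = 0.20 (p = 0.173) with that difference.

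Ets1, an ETS factor of lymphoid cells, was low where Erg was high. It was chosen after all genes had been ranked by their correlation with Erg over the 47 arrays. Its rho was -0.78 (permutation p = 1e-05, the smallest the permutations can give; adjusted p = 0.000522 over 18177 other genes) and its r was -0.78 (permutation p = 1e-05), or -0.75 without the 2 arrays farthest from the median Erg value. The relation was not singular: 3313 genes passed the same adjustment, 2090 rising with Erg and 1223 falling, and 16 had a rho at least as large in size as that of Ets1, itself included. Ets1 ran from 6.11 to 10.10. Of the 47 arrays, 17 had Erg above log2 7, 34 had Ets1 above it, 6 had both and 2 had neither. The 17 other tested ETS genes had a median rho of -0.22 with Erg, from -0.53 to 0.58. This relation uses no label.

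**Figure D4:**
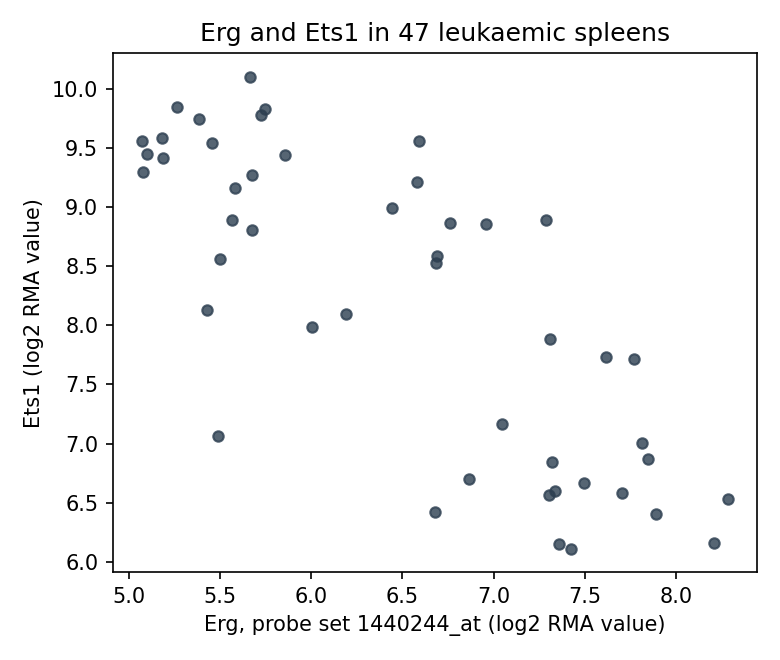
Log2 values of the brighter Erg probe set (horizontal axis) and of Ets1 (vertical axis) in 47 leukaemic spleens, 1 point per array. Ets1 is lower where Erg is higher (r = -0.78), and 6 arrays have both above log2 7.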

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

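The filter at log2 6, the fit without the sex label, the fit on arrays with matching sex labels and the Erg correlations over all 47 arrays were chosen after the data were seen. Counts of genes higher and lower with the Erg label were 0 by limma (666 at an unadjusted p under 0.05) and 0 in all 21 alternatives, as were those for sex, age and both interactions in theirs. For line, 1 gene passed in the 23 arrays whose sex label matched: Crip1, named after its value was seen, higher in line 6113 by 0.97 ± 0.13 (adjusted p = 0.00967), against 0.67 (adjusted p = 0.999) over all 47. The Erg difference kept its sign in 20 of 21 alternatives, from 0.24 to 0.97, and was -0.058 in those 23 arrays. Its limma p, adjusted over all genes or probe sets tested, was never under 0.576. The cause of either change was not tested. The age difference stayed past the threshold in all 5 alternatives (12.3 to 20.1). The correlation of Erg fold changes between the lines ranged from -0.21 to -0.19. No component test passed with only the most variable genes (smallest adjusted p = 0.680).

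List calls moved most. The 5 calls at the preset correlation became 0 with an estimated correlation and 0 with fry, which allow for the correlation between members, 11 at the log2 7 filter, 9 at log2 6, 8 with age as a covariate, 8 with the tumour identifier block, 2 in line 6070 and 3 in labelled males. At the log2 7 filter, which left 6, 3, 4, 10 and 9 members of the B cell, plasma cell, dendritic cell, stroma and hypoxia lists, their medians were -0.51, -0.61, -0.17, 0.19 and 0.14, and at log2 6 -0.27, -0.14, -0.16, 0.11 and 0.11, all larger in size than over all members, many of which lie near the floor. With an estimated correlation and fry the list medians are unchanged by construction: -0.12 for B cell, -0.037 for plasma cell, -0.022 for dendritic cell and MHC class II, 0.023 for stroma and endothelium and 0.054 for hypoxia and glycolysis. Calls also ended as follows, with the median log2 difference; the cause was not tested, beyond there being fewer arrays in the subsets. The hypoxia list was not called at the log2 6 filter (adjusted p = 0.0804). The stroma list was at 0.023 with age as a covariate, 0.016 in mice with 09 and 0.025 in line 6113. The plasma cell list was at -0.019 with the identifier block and -0.029 with the lymphocyte covariate, under which the dendritic cell list was at -0.019. In line 6070 the B cell, plasma cell, dendritic cell and hypoxia lists were at -0.060, -0.022, -0.027 and 0.014. The hypoxia list was at 0.088 in line 6113 and 0.066 in labelled females. In labelled males the B cell, plasma cell, stroma and hypoxia lists were at -0.060, -0.012, 0.011 and 0.038, and the dendritic cell list turned to 0.0025. In the 23 arrays with matching sex labels the B cell and plasma cell lists were at -0.070 and -0.010, and the dendritic cell list turned to 0.027.

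Of 801 values of 40 named genes, 784 kept their sign and 17 turned, in 11 genes, of which none passed a threshold in any alternative. Stfa3 was at 0.0011 in mice with 09, 0.016 in line 6113 and 0.053 in labelled females, and Epx at 0.091, 0.099 and 0.092. In line 6113, Ccl5 was at 0.030, Ptprv at -0.0024 and Ddx3x at -0.011. In labelled males, Cdk1 was at 0.026, Bub1b at 0.022, Csf2rb at -0.22 and Ets1 at 0.50. In the 23 arrays with matching sex labels, Uros was at 0.080, Camp at 0.11, Bub1b at 0.050 and Ets1 at 0.032. Among relations of the Erg level, 3 passed as reported and 3 with the dimmer probe set, 6 without the 2 farthest arrays, and 6 of the 10 lists over all 47 arrays. No paired analysis was possible because replicate numbers only follow the order of deposit and pair no mice. Signal over background limits dim genes most: 2718 genes passed the log2 7 filter against 18178 at log2 5.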

Other observations

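The tests of the sex labels, of degraded RNA, of all labels by genes at an unadjusted p, and of random splits for Erg, line and sex were chosen after the result was seen, and so were the genes named in this part; the lists of precursor and mature cells were written after the component weights were seen and before their tests.

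Precursor lymphocyte genes were bright in some spleens that carry a myeloid diagnosis. Vpreb1 was above log2 7 in 15 of 47 arrays (up to 11.06), Igll1 in 14, the recombinase gene Rag1 in 12 and Dntt, which adds bases at recombined joints, in 6. Rag2, the partner of Rag1, was above it in 0 arrays (highest 6.33). Of T lineage genes, Dtx1 was above it in 7 arrays, Notch1 in 6 and Ptcra, the pre-T cell receptor chain, in 3. The mature B cell genes Ms4a1 and Bank1 were each above it in 8 arrays, and Cr2, Fcer2a and Cxcr5 in 0. The mature T and NK genes Ccl5, Nkg7 and Ms4a4b were each above it in 5.

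If B cells of the normal spleen brought the precursor RNAs, the precursor B list would follow the mature B list. Here rho was 0.60 (95% bootstrap interval 0.31 to 0.80, permutation p = 4e-05) and r 0.66, between the levels set for and against. Tumour cells that expressed genes of both lists would also give a positive rho, so the test cannot decide and this stays open. For T cells, rho between the precursor T list and the mature T and NK list was 0.73 (0.54 to 0.85), past the level set for this source. However, r was only 0.43 and most mature T genes lay near the floor. Tumour cells that expressed genes of both lists would give the same, so T cells as a source stay open too. Degraded RNA would tie the precursor B list to the 3′ minus 5′ difference; rho was -0.29 (-0.56 to 0.0077), which also stays open. Of the tested members, 9 of 10 mature B genes, 7 of 10 mature T and NK genes and 1 of 7 precursor T genes also stand in the B or T lists fixed earlier, and Rag1, Rag2 and Dntt stand in both precursor lists. No biological explanation was tested, since the labels give no group by lineage.

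Ets1 and Erg may mark different states of these tumours, as a hypothesis drawn from the same data. A candidate explanation without such states is that lymphocytes of the spleen bring Ets1 and are fewer where Erg is high. The relation would then lose its sign once the T and NK, B and plasma cell means are regressed out of both; the partial rho was -0.71 (permutation p = 1e-05, the smallest the permutations can give). This argues against lymphocytes, as far as these 3 list means measure them, as the whole source. Other cell types were not tested.

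For the mismatch between sex labels and transcripts, single labelling errors would leave few disagreements, but 24 of 47 arrays disagreed, within the range of random pairing. Loss of a sex chromosome or of Xist would leave arrays without either signal, but all 24 carried the complete pattern of the other sex. Labels and arrays paired out of order across the series would give chance matches with equal totals, and both were seen (23 matches), so this stays open and may extend to the Erg, line and age labels. Of 65 re-orderings of the label list, the best gave 35 matches, and in 5.69% of 10000 shuffles the best of the same orderings matched as many, so none was used.

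For the absence of genes past the threshold by the Erg label, too few arrays is argued against only within the reach of the simulation. In simulated data of the same design, 97.65% of genes shifted by 1 log2 unit in every labelled array were recovered. Those genes had a mean above log2 6 and were drawn at random, not by their spread. For genes as variable as Erg (SE 0.29, against a median of 0.031 over all tested genes), too few arrays stays open. Whether only the sex labels are out of order, with the Erg labels right, could not be told: 59 of 100 random splits gave as many genes at an unadjusted p under 0.05 as the 666 of the Erg label (highest other 4066). A scrambled label and a label without an effect on expression would both give such a count. Erg itself was higher with the label by 0.56 (limma, unadjusted p = 0.0580) and above log2 7 in 13 of 26 arrays against 4 of 21. That p is not under 0.05, so Erg did not settle the question. The difference of -0.058 in the 23 arrays with matching sex labels cannot bear on it. Random pairing gives about as many matches, so a match does not pick out arrays whose Erg label is right. That tumours with and without the insertion express alike stays open, as untested.

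For the gene counts, random splits could not decide on chance, since a count of 0 is reached by every split. By limma, 0 genes were higher and 0 lower with the Erg label (100 of 100 splits for each, by construction), and the highest other split called 349 higher and 430 lower. For line and sex, also 0 by limma with 100 of 100 splits, the highest others called 1579 and 1739 genes, and for the interactions of the Erg label with line and with sex, again 0 and 100 of 100, they called 436 and 164. Counts at an unadjusted p under 0.05 can be compared: 73 of 100 splits gave at least the 540 genes of line (highest other 4709), 80 at least the 460 of sex (4738), 16 at least the 1286 of the interaction with line (3418) and 24 at least the 1079 of that with sex (4029), so chance could not be excluded for these. Splits of the age label were not run. Of the other splits, 3 for Erg, 3 for line, 1 for sex, 4 for the interaction with line and 1 for that with sex called any gene. Splits that call many genes point to a structure of the samples, and which structure they follow was not tested. For the 5 lists called for the Erg label at the preset correlation, 77 of 100 splits called as many and the highest other called 13, so chance could not be excluded; the list calls for line, sex and age were not compared with splits.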
